A study of Citrus maxima with 12 samples.

How the data were processed

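Messenger RNA was measured by sequencing in 12 libraries of pomelo fruit, 3 each from control and diseased fruit of the cultivars Jinsha and Jinlan. Per the labels, RNA was extracted with a Qiagen column kit and made into libraries with a SMARTER kit. Libraries were placed in groups by the cultivar and treatment in the labels. Replicates carry numbers 1 to 3 per group, and the labels do not say whether they came from separate fruits or trees, so p-values measure only the spread between these samples, which may be technical.

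The authors deposited one table of FPKM values per gene and library, with no counts, so sequencing depth is unknown and no counting interval or detection limit is given. FPKM divides fragments by transcript length and by the library's mapped fragments, which makes each value relative to all other transcripts in its library. The aligner, the genome build, the annotation and the quantification tool are not given in the sources used here. A value of 0 is reported as listed at 0, since it can also be a failed estimate. No genome or annotation was used, and 0 identifiers were matched to a name. Tests of gene lists by function, chosen before the data were examined together with the comparisons, the test, the alternatives and the rule for named genes, therefore could not be run. Metabolite measurements named in the series title were not analysed here.

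Any pair of libraries shared at most 0.00479% of their nonzero values, so no library was treated as a copy of another. Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept, which left 17120 of 32863. A linear model with 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Genes with an adjusted p below 0.05 are referred to as called, and as rising or falling. A second count asked in addition for a change of at least 2-fold. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The comparisons were diseased against control fruit in each cultivar, the difference between these changes (interaction), and Jinlan against Jinsha in control and in diseased fruit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

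Because identifiers had no names, at most 2 identifiers per direction and comparison are named, also where a count is small. They had the highest or lowest log2 fold change among called genes with at least 5 FPKM in the mean of the higher group and no overlap between the libraries of the groups. For the interaction, the libraries of control and diseased fruit had to be free of overlap in both cultivars.

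The fit was tested on simulated data with 16706 genes. For each comparison 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold in 1 group, and the others were left unchanged. In the Jinsha disease comparison 97.0% of genes changed 2-fold and 77.6% of those changed 1.5-fold were recovered, in Jinlan 91.0% and 76.1%, and in the interaction 82.1% and 53.7%. For the cultivar difference the shares were 100% and 85.1% in control fruit and 95.5% and 77.6% in diseased fruit. Unchanged genes made up 8.5% of the simulated calls for disease in Jinsha (17 of them beside 183 recovered) and 7.29% in Jinlan (14 beside 178). For the interaction they made up 6.63% (11 beside 155). For the cultivar difference they made up 5.47% (11 beside 190) in control and 7.65% (15 beside 181) in diseased fruit. Each share came from 1 simulation, with the same simulated spread in all comparisons, and all lay above the 5% that the threshold sets. In the measured data 57.9% to 67.3% of the genes were called, far more than were changed in the simulation. The simulated shares therefore do not carry over to the measured data.

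Several descriptions were chosen after the data had been seen: genes passing from below 1 to at least 5 FPKM, shares of total FPKM, identifier prefixes, adjacent identifier numbers and the position of each library. The position of a library is its distance from its own group's mean as a share of the distance to the other group of its cultivar, on the FPKM scale. Its genes had at least 20 FPKM in the mean of the higher group, a 4-fold difference and values there no more than 25% above the lowest, all from the other 2 replicate numbers.

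Alternatives were other pseudocounts (0.1 and 5), other filters, scaling to a fixed sum, median-ratio scaling, quantile normalization, fits to the compared groups alone, other variance models, library weights, the replicate number as a block, and leaving out each library in turn. Fits without Jinlan control replicate 3 and Jinlan disease replicate 3 together were added after the data had been seen.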

Results

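RNA sequencing was used to measure gene expression in fruit of pomelo (Citrus maxima), a large-fruited citrus species. Fruit of the cultivars Jinsha and Jinlan was sampled as control fruit and as fruit with yellow spot disease, in 4 groups of 3 libraries each. Expression was given as FPKM (sequenced fragments scaled to transcript length and to the mapped fragments of the library) for 32863 gene identifiers, of which 7651 were listed at 0 in all 12 libraries. Between 16054 and 16456 genes per library reached 1 FPKM, and the FPKM values of a library summed to between 550055 and 575107. The identifiers were not paired with gene names or products, so genes are given by identifier and their functions are not stated.

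Expression profiles were closer within groups than between them. Over the 17120 genes tested, Pearson's r between libraries was 0.9916 to 0.9947 within groups and 0.9248 to 0.9636 between groups, with genes as the data points. The first principal component held 38.8% of the variance and separated the diseased Jinlan libraries from the others. The second component, with 33.8%, separated control from diseased fruit in both cultivars, and the third held 17.9%. Jinlan control replicate 3 lay nearer to the diseased Jinlan libraries on the first component (7.51) than Jinlan control replicates 1 (-1.19) and 2 (-3.24).

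**Figure D1:**
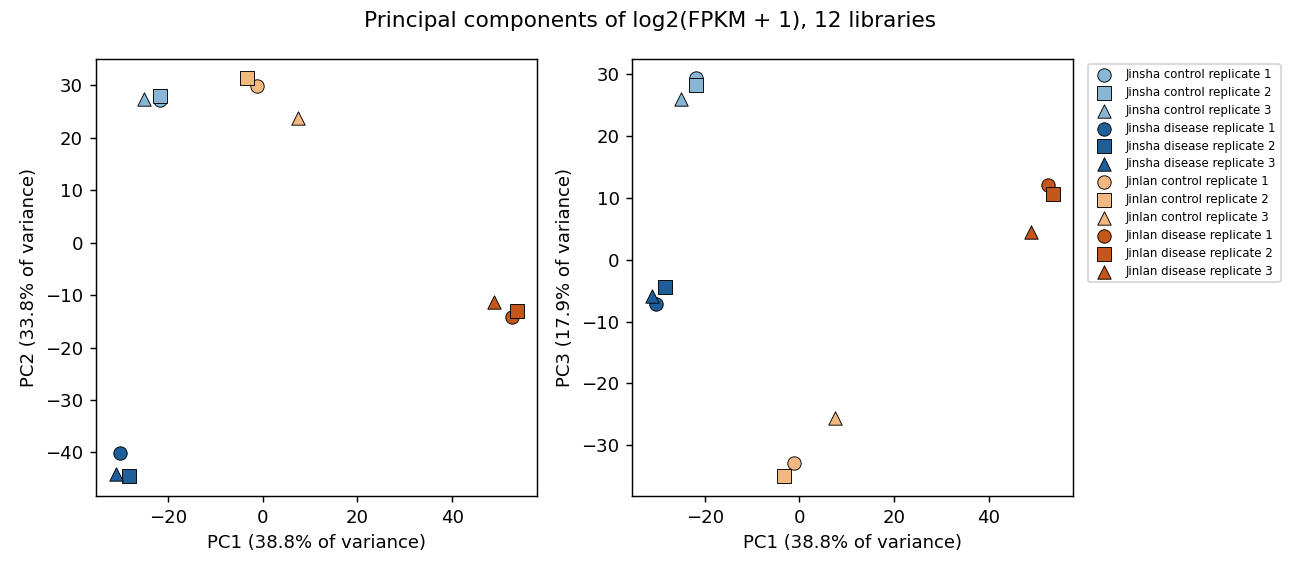
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), with the percent of variance on each axis; colours mark the 4 groups and symbols the replicate numbers. The libraries fall into their 4 groups, and Jinlan control replicate 3 sits at 7.51 on the first component.

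To find which genes differed between diseased and control Jinsha fruit, the groups were compared within this cultivar. Among genes changed at least 2-fold, decreases outnumbered increases, with 930 genes lower and 392 higher in diseased fruit. Cg1g003320 rose from 0.278 ± 0.137 to 102 ± 8.81 FPKM (SD, n = 3 per group), and Cg2g015260 rose from 0.165 ± 0.0847 to 90.6 ± 49.6 FPKM. Cg1g005260 fell from 55.6 ± 1.26 to 1.09 ± 0.336 FPKM. Cg4g019170 fell from 53.6, 54.9 and 241 FPKM in the control libraries to 0.453 FPKM in diseased replicate 2, and was listed at 0 in diseased replicates 1 and 3.

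The 930 genes that fell made up 9.83 ± 0.26% of the total FPKM of control Jinsha libraries and 3.05 ± 0.17% of that of diseased libraries (SD, n = 3). The 392 genes that rose went from 2.22 ± 0.057% to 6.63 ± 0.12%. These shares describe genes chosen by the same comparison. Expression went from below 1 FPKM in every control library to at least 5 FPKM in every diseased library for 16 genes, and the reverse held for 14 genes.

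At an adjusted p below 0.05 without a fold threshold, limma called 4668 genes higher and 5290 lower in diseased Jinsha fruit. This balance turned with scaling, to 5061 higher and 5044 lower after median-ratio scaling and 5578 and 4490 after quantile normalization. The log2 fold changes on the log2(FPKM + 1) scale were 6.34 (SE 0.17, adjusted p = 3.2e-11) for Cg1g003320 and 6.15 (SE 0.67, adjusted p = 5.16e-06) for Cg2g015260. They were -6.32 (SE 0.64, adjusted p = 2.84e-06) for Cg4g019170 and -4.77 (SE 0.13, adjusted p = 4.03e-11) for Cg1g005260. The sizes depended on the pseudocount: with 0.1 in place of 1 the same 4 values, in this order, were 8.15, 8.32, -8.98 and -5.59 and 1428 genes were at least 2-fold lower, and with 5 they were 4.34, 4.07, -4.21 and -3.32, with 221 genes at least 2-fold higher and 422 lower. Without Jinsha control replicate 3 the value for Cg4g019170 was -5.61.

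**Figure D2:**
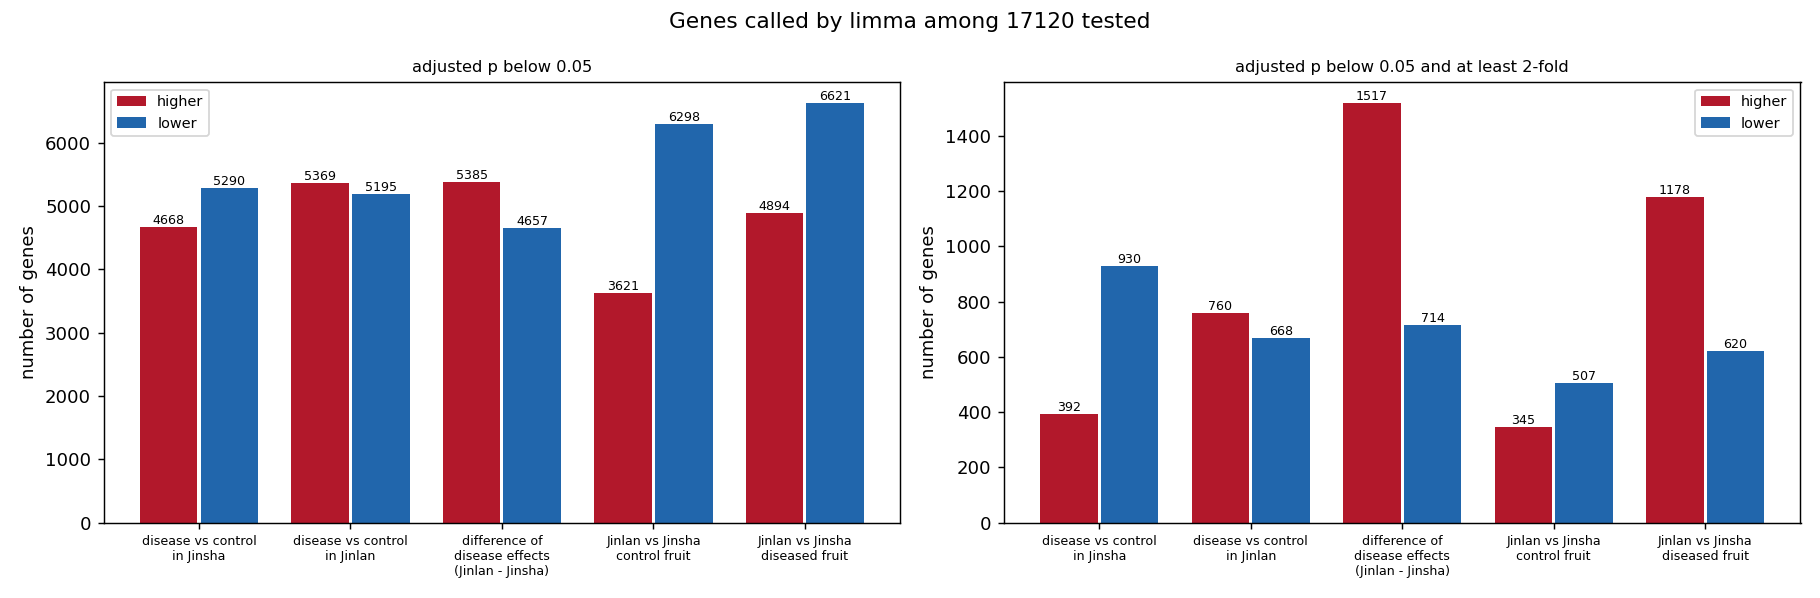
Number of genes called higher (red) and lower (blue) by limma in each comparison, at adjusted p below 0.05 (left) and with a fold change of at least 2 in addition (right). In Jinsha, 930 genes fell and 392 rose at least 2-fold, and in Jinlan 668 fell and 760 rose.

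The same comparison was made in Jinlan fruit. At least 2-fold, 760 genes were higher and 668 lower in diseased fruit. CgUng021670 rose from 1.37 ± 1.51 to 55 ± 9.3 FPKM (SD, n = 3 per group), and Cg4g022200 rose from 9.81 ± 12.4 to 139 ± 33.1 FPKM. Cg9g006330 fell from 74.5 ± 4.79 to 4.21 ± 1.35 FPKM. Cg4g019170, which also fell in Jinsha, went from 451, 621 and 106 FPKM in control replicates 1 to 3 to 0.176 and 1.25 FPKM in diseased replicates 1 and 2, and was listed at 0 in diseased replicate 3.

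The 668 genes that fell took 11.2 ± 0.67% of the total FPKM of control Jinlan libraries and 3.69 ± 0.45% of that of diseased libraries, and the 760 genes that rose went from 3.36 ± 0.59% to 9.57 ± 0.67% (SD, n = 3, genes chosen by the same comparison).

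Jinlan control replicate 3 lay part of the way towards diseased fruit. Over 79 genes at least 4-fold higher in diseased than in control Jinlan fruit, picked from replicates 1 and 2, its expression stood at a median of 0.146 of the distance from control to diseased levels (quartiles 0.132 to 0.156). Over 90 genes lower in diseased fruit the median was 0.166 (quartiles 0.108 to 0.204). In Jinlan disease replicate 3 the same measure towards control fruit was 0.0199 for the 90 genes higher in control fruit and 0.221 for the 79 genes lower in it. No gene went from below 1 FPKM in every Jinlan control library to at least 5 FPKM in every diseased library, and 4 went the other way. The numbers were 10 and 8 without both of these libraries, 1 and 6 without both Jinlan replicates 1, and 0 and 8 without both Jinlan replicates 2.

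**Figure D3:**
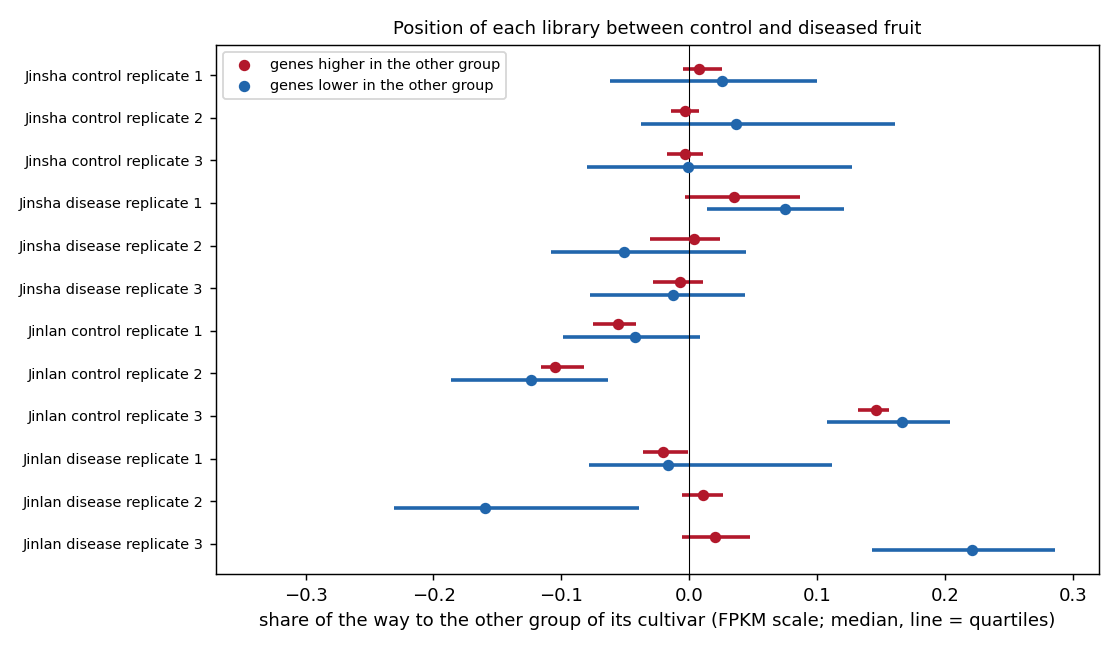
Position of each library between the control and diseased group of its cultivar on the FPKM scale (0, own group; 1, other group), as the median (point) and quartiles (line) over genes at least 4-fold higher (red) or lower (blue) in the other group, picked from the other 2 replicate numbers. Jinlan control replicate 3 lies at 0.146 and 0.166, and Jinlan disease replicate 3 at 0.0199 and 0.221.

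With limma, 5369 genes were called higher and 5195 lower in diseased Jinlan fruit at any fold (5343 and 5339 after median-ratio scaling, 5300 and 5365 after quantile normalization). The log2 fold changes were 4.75 (SE 0.44, adjusted p = 1.28e-06) for CgUng021670, 4.36 (SE 0.59, adjusted p = 3.38e-05) for Cg4g022200, -7.82 (SE 0.64, adjusted p = 5.07e-07) for Cg4g019170 and -3.89 (SE 0.15, adjusted p = 1.92e-09) for Cg9g006330. Without Jinlan control replicate 3 the values were 5.31 for Cg4g022200 and -8.58 for Cg4g019170, without Jinlan control replicate 2 that for Cg4g022200 was 3.62, and without both Jinlan replicate 3 libraries 901 genes were higher and 769 lower at 2-fold. With a pseudocount of 5 the 4 values in the order first given were 3.25, 3.58, -5.86 and -3.12, with 377 genes higher and 364 lower at 2-fold, and with 0.1 those for CgUng021670 and Cg4g019170 were 6.03 and -9.86.

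**Figure D4:**
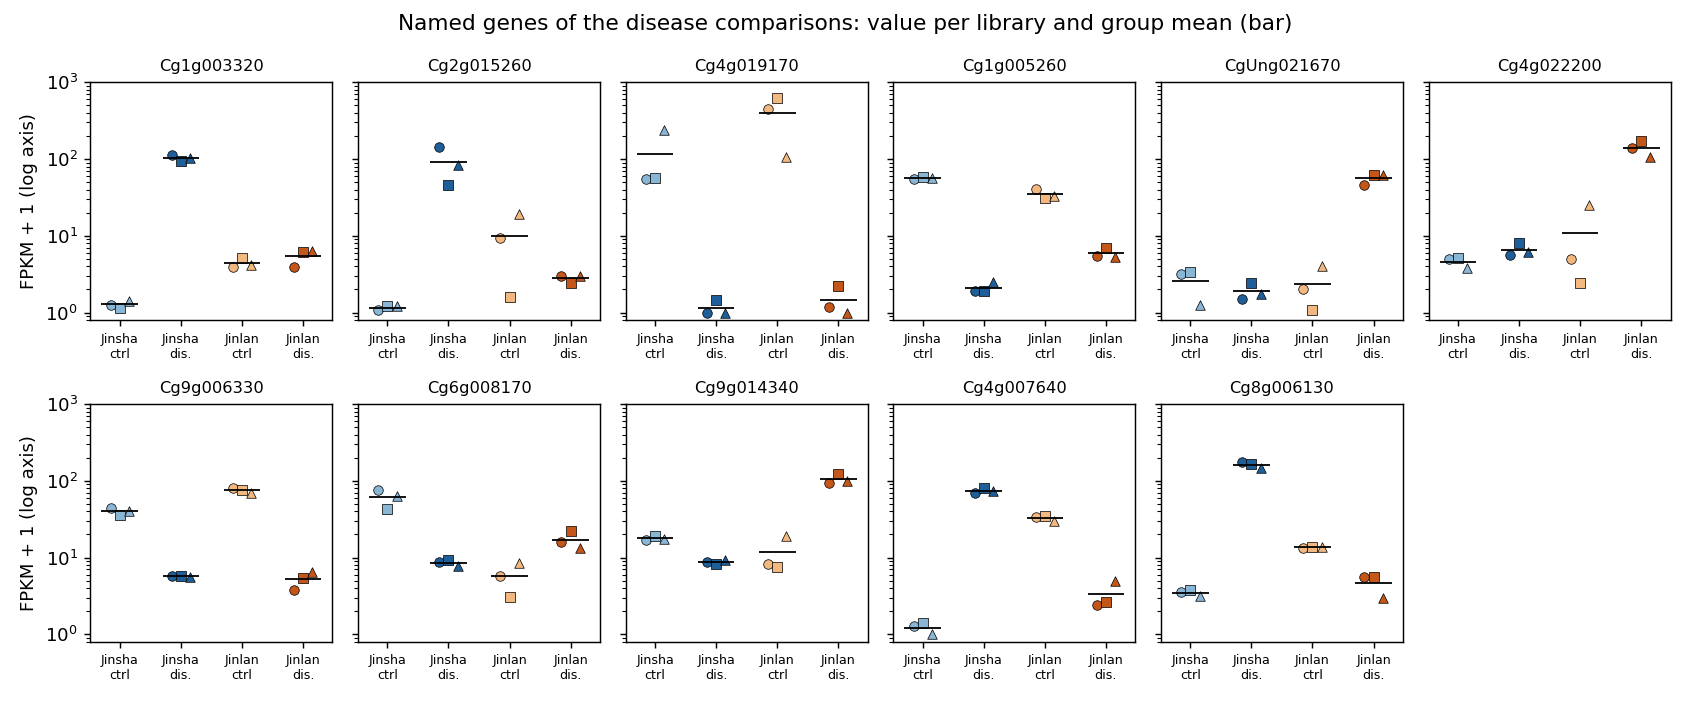
FPKM + 1 (log axis) of 11 genes in the 12 libraries, with the arithmetic group mean as a bar; circles, squares and triangles are replicates 1, 2 and 3. Cg4g019170 fell in both cultivars, whereas Cg4g007640 and Cg8g006130 rose in diseased Jinsha fruit and fell in diseased Jinlan fruit.

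The disease comparisons of the 2 cultivars were then set against each other. They share no library, but each gene's spread came from the same fit to all 12 libraries. At 2-fold, 280 genes fell in both cultivars, 7.72 times the 36.3 that independent lists of these sizes would share, and 50 rose in both, 2.87 times the 17.4 of independent lists. Cg4g019170, Cg9g006330 and Cg1g005260 fell in both, with log2 fold changes of -2.80 in Jinsha and -3.89 in Jinlan for Cg9g006330 and of -4.77 and -2.54 for Cg1g005260. Opposite changes of at least 2-fold were found for 35 genes that rose in Jinsha and fell in Jinlan, 2.29 times the 15.3 of independent lists. They were also found for 58 genes that fell in Jinsha and rose in Jinlan, 1.4 times the 41.3 of independent lists. An excess over independent lists was thus not limited to genes changed the same way, though it was largest for genes lower in both.

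The overlaps at 2-fold had adjusted p = 2.38e-184 for genes lower in both, 4.43e-11 for genes higher in both, and 1.15e-05 and 0.00861 for the 2 opposite classes in the order given (Fisher's exact test, two-sided, 8 tests; unadjusted p = 2.98e-185, 1.66e-11, 7.2e-06 and 0.00861). At any fold, 1605 genes were higher in both cultivars (1464 for independent lists, adjusted p = 4.42e-07) and 2070 were lower in both (1605 for independent lists, adjusted p = 1.16e-60). The opposite classes at any fold lay below independent lists, with 1346 genes higher in Jinsha and lower in Jinlan (1416 for independent lists, adjusted p = 0.00861) and 1567 the other way round (1659, adjusted p = 0.00139). Fisher's exact test takes genes as independent, which they are not, so these p-values can be too small. The spread per gene that both comparisons share can also add to the overlap. With fits to the compared groups alone, 282 genes were lower and 50 higher in both cultivars at 2-fold. Among the 6588 genes called in both cultivars 55.8% changed in the same direction. Across all tested genes the log2 fold changes of the cultivars had Pearson's r of 0.201 and Spearman's rho of 0.111, and genes are not independent replicates. With pseudocounts of 0.1 and 5 the number lower in both at 2-fold was 432 and 148, and the number higher in both was 115 and 14.

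Genes changed in one cultivar were then followed in the other, where a call at any fold was counted. Of all 17120 tested genes, 5369 rose, 5195 fell and 6556 were not called in Jinlan. In Jinsha 4668 rose, 5290 fell and 7162 were not called. Part of each number that follows would thus be found among any tested genes. Of the 392 genes that rose at least 2-fold in Jinsha, 146 also rose in Jinlan, 118 fell and 128 were not called. Of the 930 that fell in Jinsha, 570 fell in Jinlan, 165 rose and 195 were not called. Of the 760 that rose in Jinlan, 157 rose in Jinsha, 263 fell and 340 were not called, and of the 668 that fell in Jinlan, 476 fell in Jinsha, 89 rose and 103 were not called. Among the 14 Jinsha genes that went from at least 5 FPKM to below 1 FPKM, 13 were also called lower in Jinlan. Among the 16 that went the other way 3 were also called higher. Of the 4 Jinlan genes that went from at least 5 FPKM to below 1 FPKM, 1 was also called lower in Jinsha.

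Whether the disease effect itself differed between the cultivars was tested as an interaction, the Jinlan change minus the Jinsha change. Cg4g007640 rose in Jinsha from 0.278 and 0.392 FPKM in control replicates 1 and 2 (listed at 0 in replicate 3) to 73.4 ± 5.22 FPKM, and fell in Jinlan from 31.7 ± 2.76 to 2.31 ± 1.44 FPKM (SD, n = 3). Cg8g006130 rose in Jinsha from 2.48 ± 0.277 to 161 ± 15.2 FPKM and fell in Jinlan from 12.7 ± 0.207 to 3.72 ± 1.49 FPKM. Cg6g008170 took the opposite course, from 59.6 ± 16.2 to 7.61 ± 0.757 FPKM in Jinsha and from 4.77 ± 2.69 to 16.2 ± 4.42 FPKM in Jinlan. Cg9g014340 fell from 16.8 ± 0.972 to 7.78 ± 0.564 FPKM in Jinsha and rose from 10.7 ± 6.59 to 104 ± 14.7 FPKM in Jinlan.

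The interaction was called by limma for 10042 genes, 58.7% of those tested, with 5385 higher and 4657 lower in Jinlan relative to Jinsha. After quantile normalization the balance was turned, with 4677 higher and 5453 lower. At 2-fold, 1517 were higher and 714 lower. The log2 differences were -9.32 (SE 0.31, adjusted p = 4.13e-10) for Cg4g007640, -7.14 (SE 0.26, adjusted p = 9.13e-10) for Cg8g006130, 4.45 (SE 0.43, adjusted p = 2.7e-06) for Cg6g008170 and 4.30 (SE 0.36, adjusted p = 9.2e-07) for Cg9g014340. For Cg4g019170 the difference was -1.50 (SE 0.90, adjusted p = 0.172) and was not called, but it was called at -2.21 without Jinsha control replicate 3, at -2.26 without Jinlan control replicate 3 and at -2.03 without both Jinlan replicate 3 libraries. The interaction was called for 341 of the 392 genes that rose and 759 of the 930 that fell in Jinsha at 2-fold, and for 705 of the 760 that rose and 496 of the 668 that fell in Jinlan. These genes were picked by a change that is itself a term of the interaction, so their high shares were partly set by that choice. With a pseudocount of 5 the differences for Cg4g007640, Cg8g006130, Cg6g008170 and Cg9g014340 were -6.25, -5.51, 3.46 and 3.62, with 723 genes higher and 388 lower at 2-fold, and with 0.1 those for Cg4g007640 and Cg8g006130 were -11.98 and -7.80.

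**Figure D5:**
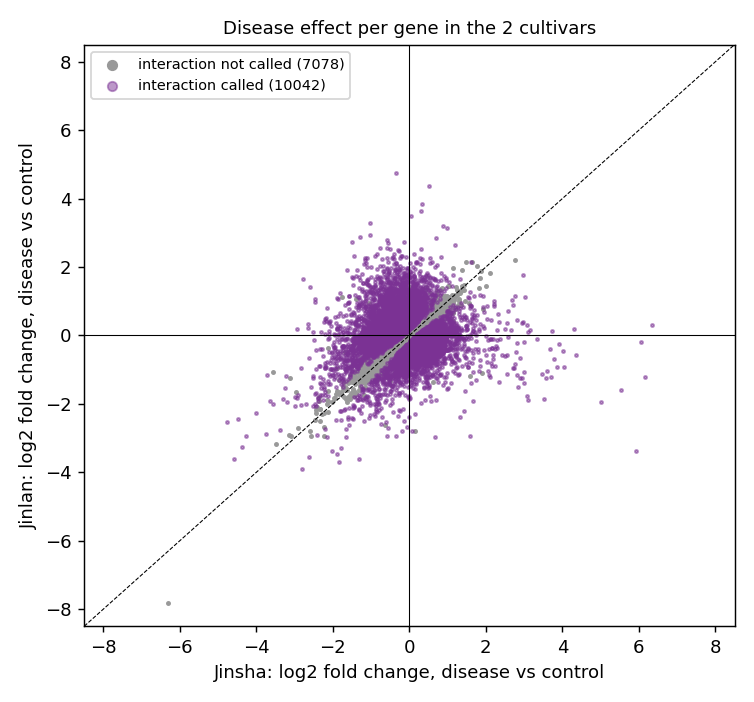
Log2 fold change of diseased against control fruit in Jinsha (horizontal) and Jinlan (vertical) for the 17120 tested genes, with genes called by the interaction in purple and the others in grey; the dashed line marks equal changes. Of the tested genes, 10042 were called by the interaction.

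In control fruit the cultivars differed at 345 genes higher and 507 lower in Jinlan by at least 2-fold, a balance that turned after median-ratio scaling (426 and 400) and quantile normalization (421 and 412). Cg4g007640 was higher in Jinlan, at 31.7 ± 2.76 FPKM, than in Jinsha, at 0.278 and 0.392 FPKM in replicates 1 and 2 and listed at 0 in replicate 3. Cg4g009330 was at 31.2 ± 1.29 FPKM in Jinlan and 1.27 ± 0.698 FPKM in Jinsha (SD, n = 3). Cg6g008170 was lower in Jinlan (4.77 ± 2.69 FPKM) than in Jinsha (59.6 ± 16.2 FPKM), and Cg5g038920 was at 0.701 ± 0.136 FPKM in Jinlan and 11.4 ± 3.73 FPKM in Jinsha.

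With limma, 3621 genes were called higher and 6298 lower in Jinlan control fruit at any fold. The any-fold split also depended on scaling: 36.5% of the called genes were higher with the FPKM values as given, 50.5% after median-ratio scaling and 50% after quantile normalization. The log2 differences were 4.75 (SE 0.22, adjusted p = 8.25e-09) for Cg4g007640, 3.87 (SE 0.18, adjusted p = 9.44e-09) for Cg4g009330, -3.47 (SE 0.30, adjusted p = 1.18e-06) for Cg6g008170 and -2.83 (SE 0.21, adjusted p = 4.13e-07) for Cg5g038920. With a pseudocount of 0.1 the values for the same genes were 6.90, 4.64, -3.75 and -3.81, with 569 genes higher and 860 lower at 2-fold, and with 5 they were 2.81, 2.53, -2.73 and -1.50, with 165 higher and 191 lower.

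In diseased fruit the cultivars differed at 1178 genes higher and 620 lower in Jinlan by at least 2-fold. CgUng021670 was at 55 ± 9.3 FPKM in Jinlan and 0.888 ± 0.494 FPKM in Jinsha, and Cg4g022200 at 139 ± 33.1 and 5.62 ± 1.21 FPKM (SD, n = 3). Cg1g001610 was at 0.353 ± 0.103 FPKM in Jinlan and 73.2 ± 14.2 FPKM in Jinsha, and Cg8g006130 at 3.72 ± 1.49 and 161 ± 15.2 FPKM. In control fruit CgUng021670 and Cg4g022200 were not called between the cultivars (adjusted p = 0.718 and 0.444). The log2 difference of Cg4g022200 there was 0.55, and it was called at 1.28 without Jinlan control replicate 2. Without Jinlan control replicate 3 its sign turned, to -0.4, and it was not called.

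With limma, 4894 genes were called higher and 6621 lower in diseased Jinlan fruit at any fold. The numbers were 5593 higher and 5766 lower after median-ratio scaling, and 5037 higher and 6459 lower after quantile normalization. The log2 differences were 4.91 (SE 0.44, adjusted p = 6.12e-07) for CgUng021670, 4.39 (SE 0.59, adjusted p = 2.34e-05) for Cg4g022200, -5.76 (SE 0.12, adjusted p = 3.89e-12) for Cg1g001610 and -5.16 (SE 0.18, adjusted p = 2.34e-10) for Cg8g006130. With a pseudocount of 5 these values were 3.34, 3.75, -3.85 and -4.27, with 590 genes higher and 335 lower at 2-fold, and with 0.1 those for CgUng021670 and Cg1g001610 were 5.90 and -7.34.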

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

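The tests of exchanged labels and of the positions of single libraries were chosen only after the results had been seen, as were the fits without both Jinlan replicate 3 libraries. The disease effect differed between Jinsha and Jinlan by the interaction test for 10042 genes, 58.7% of those tested, and for 13 of the 14 named genes. The named genes were picked as extremes of the comparisons, the interaction among them, so their high share was largely set by that choice and adds no support. The log2 differences, Jinlan minus Jinsha, were -9.32 for Cg4g007640, -7.38 for Cg2g015260, -7.14 for Cg8g006130, -6.97 for Cg4g009330, -6.23 for Cg1g001610, -6.04 for Cg1g003320 and -1.09 for Cg9g006330. They were 5.11 for CgUng021670, 4.45 for Cg6g008170, 4.30 for Cg9g014340, 3.85 for Cg4g022200, 2.23 for Cg1g005260 and 1.12 for Cg5g038920. Without Jinlan control replicate 2 the difference was -8.40 for Cg2g015260 and 3.11 for Cg4g022200, and without Jinlan control replicate 3 it was -6.61 and 4.80.

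If the cultivar labels of the diseased libraries had been exchanged, genes at least 4-fold apart between the cultivars in control fruit would be turned around in diseased fruit, but 37 of the 48 that were called there (77.1%, exact 95% interval 62.7 to 88.0% with genes taken as independent) kept their direction, as did 464 of 666 (69.7%) genes at least 2-fold apart. The 4 genes at least 8-fold apart, Cg4g007640, Cg4g009330 and Cg6g008170 among them, all turned around (Cg6g008170 was at 0.97 in diseased fruit, and at 0.78 and not called without Jinlan disease replicate 2), so the majority of these genes argues against an exchange and its most changed members do not. Scaling as the whole cause was argued against as well, since at least 90.8% of the interaction calls stayed called in the same direction after median-ratio scaling and quantile normalization, and so were the intermediate libraries, since 90.3% did so without both Jinlan replicate 3 libraries. Of 100 drawn splits of the cultivar labels within treatments, 1, the real one, gave as many called genes (10042, highest other 6224), but 83 splits called 0 genes, since mixing the cultivars puts their own difference into the spread, so these splits do not decide whether chance can be excluded. A cultivar difference in the response stays open as a hypothesis, as does a difference in the stage or severity of disease, which the labels do not give.

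For the other comparisons the 6 libraries allow 10 splits, too few for a share under 0.05. The real split called 9958 genes for disease in Jinsha (highest other 3) and 10564 for disease in Jinlan (highest other 0). It called 9919 between cultivars in control fruit (highest other 0) and 11515 in diseased fruit (highest other 0). Every other split mixes the groups compared and puts their own difference into the spread, which by itself leaves few calls. These splits therefore do not decide whether chance can be excluded.

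Jinlan control replicate 3 lay at a median of 0.146 of the way to diseased fruit, which argues against a swapped label, since a diseased library would lie near 1. The shares from genes higher and lower in diseased fruit differed by -0.02. A share between 0.5 and 2 times the median was found for 98.7% of the genes higher in diseased fruit and 83.3% of those lower. An even admixture of diseased Jinlan material is therefore a candidate explanation. Not every gene followed it. Cg4g019170 was at 106 FPKM in this library, against 451 and 621 FPKM in Jinlan control replicates 1 and 2. Cg2g015260 was at 18.1 FPKM, against 8.32 and 0.59 FPKM there and 1.43 to 2.02 FPKM in diseased Jinlan libraries. Material from diseased Jinsha libraries was argued against by a median share of 0.000234 over 36 genes, while for control Jinsha libraries the share of 0.019 rested on 3 genes, too few to decide. Jinlan disease replicate 3 gave shares that differed by -0.201 between genes higher and lower in control fruit, which argues against an even admixture of control material there. Mixed reads, mixed RNA and early disease in the sampled control fruit stay open for control replicate 3.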

How the results depend on the processing

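The fits without both Jinlan replicate 3 libraries were chosen only after the results had been seen. All 20 results for named genes kept their direction and their call in the 397 alternative fits that tested them. Cg1g001610 was not tested without any 1 of the diseased Jinsha libraries, since the filter on low values then left it out. These results were chosen as the largest changes without overlap, so their stability says little about other calls. In other comparisons named genes did lose calls when 1 library was left out. This held for Cg5g038920 for disease in either cultivar, for Cg9g014340 and Cg4g019170 between cultivars in control fruit, and for Cg6g008170 between cultivars in diseased fruit. The counts of called genes at any fold stayed within 1.5 times in every alternative except the added fold threshold. With a fold threshold of 2 they became 392 higher and 930 lower for disease in Jinsha, 760 and 668 in Jinlan, 1517 and 714 for the interaction, 345 and 507 between cultivars in control fruit, 1178 and 620 in diseased fruit, and 50 and 280 in both cultivars; fewer genes pass by construction. These 2-fold counts moved with the pseudocount. With 5 they were 221 and 422, 377 and 364, 723 and 388, 165 and 191, 590 and 335, and 14 and 148 in the same order, since a larger pseudocount shrinks the change of low genes. With 0.1, 1428 genes were lower in Jinsha, 569 higher and 860 lower between cultivars in control fruit, and 115 higher and 432 lower in both cultivars. Leaving out 1 library gave 657 to 867 genes higher and 635 to 714 lower at 2-fold in Jinlan, with both highest values without Jinlan control replicate 3. In Jinsha the ranges were 371 to 410 and 905 to 958. Same-numbered libraries showed no shift in a common direction: deviations of 12 same-numbered pairs correlated at -0.2 to 0.036, and in 0 pairs was this the best match. Shifts in opposite directions, as of the Jinlan replicate 3 libraries towards each other, would not be found in this way. With the replicate number as a block 4518 genes were higher and 5109 lower in Jinsha, and 5218 and 5033 in Jinlan. No named gene then lost its call in the comparison that named it. Gene lists by function, with all their alternatives, were not run because no identifier was matched to a name. Depth is unknown, so what it limits could not be assessed.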

Other observations

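The tests on adjacent identifiers and identifier prefixes were chosen only after the results had been seen, except the test of reads shared between neighbours, whose outcome was not known when it was set. Genes with adjacent identifier numbers changed together more often than shuffled calls did. Among 10774 adjacent pairs of tested genes, both members fell at least 2-fold in diseased fruit for 74 pairs in Jinsha (28.4 on average after shuffling) and 53 in Jinlan (15.8), and both rose for 27 pairs in Jinsha (6.2) and 76 in Jinlan (19.6). Of 44 tests of the identifier prefix, 0 passed adjustment and 6 had an unadjusted p below 0.05. The smallest p was that of genes that start with Cg6 among those that fell in Jinsha (7.23% against 5.26%, Fisher's exact test, two-sided, p = 0.00209, adjusted p = 0.092).

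Placement by chance was argued against by a one-sided permutation p of 1e-04 in each of the 4 tests, the smallest that 10000 shuffles can give (adjusted p = 1e-04). If neighbouring genes shared reads, their deviations within groups would correlate. These pairs were 207 distinct ones, and over the 105 with both genes at a mean of at least 5 FPKM on the log2(FPKM + 1) scale the median correlation was 0.51 (bootstrap interval 0.43 to 0.59), against 0.24 for genes changed the same way and paired at random and 0.08 for adjacent genes that did not change together, all at that minimum. Pairs with a gene below it were left out, so for them the test says nothing. The median of 0.51 lay narrowly above the limit set beforehand for shared reads, while the lower end of its interval lay below that limit. Shared reads and joint regulation of neighbours therefore cannot be told apart here, and identifier numbers are not coordinates.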
